A study of Mus musculus with 6 samples.

How the data were processed

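Single cells of the colon's longitudinal muscle and myenteric plexus were measured in 6 libraries of wild-type mice, 4 from females and 2 from males. Per the labels' protocols the tissue was digested to single cells with Actinomycin D in the medium, which stops new transcription, and droplet libraries that capture the 3 prime ends of transcripts were sequenced. The deposited tables hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization, as their values show (whole numbers, with totals that differ between barcodes). FastQC, Cell Ranger 7.0, Seurat 5.0 and the genome build GRCm38 are named per the submitters' processing notes. Their settings, the annotation, the way cells were told from empty droplets and the mouse strain are not given in the sources used here. The tables list 32285 genes and 47984 barcodes, and the lowest total of any barcode was 500 UMIs.

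Groups came from the labelled sex, and the day of the experiment and the age from the labelled dates. Replicate numbers were assigned here in the order of the samples and pair no animals. Before the data were examined, the tests, the covariates, the gene lists, the cell type markers, the rule for naming genes and the alternatives below were fixed. The alternative that leaves out male cells with Xist was chosen after seeing the data, as were the numeric thresholds of the naming of clusters, the treatment of doublets by score, and the minimum of 10 UMIs in the search for outlying libraries.

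Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. This removed 1572 barcodes with too few genes and 6299 with too many mitochondrial UMIs, and some barcodes failed both. Doublet scores were computed per library with Scrublet as held in scanpy 1.11.5. Its automatic threshold marked between 0.336% and 1.35% of the cells, so the cells with the highest scores were removed instead, up to a share of 0.8% per 1000 cells. This took 2306 cells and left 38943. Doublets of a pair of cells of the same type are not found in this way, and no correction for free RNA was made.

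Counts per cell were scaled, log-transformed and reduced to 40 principal components of 2000 variable genes with numpy 2.4.6 and scikit-learn 1.9.0. The genes of the tested lists, the sex-linked genes, and mitochondrial and ribosomal protein genes were left out of the variable genes. A graph of 20 shared nearest neighbours was clustered with leidenalg 0.10.2 at resolution 1, which gave 37 clusters. Clusters with markers of more than 1 list were split again at resolution 0.5, which gave 49. A cluster was named from 20 marker lists by the mean difference of log2(CPM + 10) from the other clusters. It needed a score of 2.6, or of 1 with a marker among its 10 leading genes, and at least 3 markers seen in 5% of its cells. A cluster stayed unnamed where another list had more markers among the leading genes, or where its cells were shallow and no marker was among those genes. A part of a split cluster also stayed unnamed where it still held markers of 2 lists. In this way 18 classes were named and 10 clusters were not. A name ending in "-like" says only that the markers fixed for that type led the cluster.

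Counts were summed per library and class, since cells are not replicates, and a class was tested where every library had at least 20 of its cells. The tests were the quasi-likelihood tests of edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Sex and day were terms of a shared fit over all 6 libraries, so that the sex term compares the sexes within 10 March and the day term compares females. The numbers of cells per class were tested with edgeR in the same design over 17 classes, without TMM and without a dispersion trend. Classes were compared with each other on 91 sums of 17 classes with the animal as a block, each class against the mean of the others. Differences between classes in the sex or day effect were tested in a joint fit with library effects. "Called" means an adjusted p under 0.05 in these fits. CPM values are relative to all UMIs of the sum. Fitted log2 fold changes carry a standard error (SE), taken as the absolute log2 fold change over the square root of the test's F value. It is thus worked back from the test and is not an estimate made by edgeR. Changes of genes with 0 to 3 UMIs in a group, and the SE of these changes, depend on edgeR's prior count and are not bounds.

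The 16 gene lists cover sex-linked genes, neurons in general, genes linked in earlier work to mesoderm-derived enteric neurons (MEN), neurotrophic and niche ligands, ligands that recruit or sustain monocytes, inflammatory cytokines and chemokines, the interferon response, MHC class II, resident muscularis macrophages, immediate early and dissociation genes, heat shock, steroid hormone response, the cell cycle, the circadian clock, adipocytes and haemoglobin. They were assembled from background knowledge. In the sex and day contrasts they were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over all lists, classes and both contrasts.

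Genes were named by a fixed rule. It names 5 sex-linked genes in any case. For sex and day over all cells it names up to 5 called genes per direction with the largest change and a mean of at least 10 CPM. In each class it names up to 3 called genes per direction with the smallest p. It names up to 4 called members of each list per class, and in the comparison of classes up to 4 members of each list with the highest CPM. Gene models without an established name were skipped. A gene named outside the rule is said to be so where it appears. Positions come from GENCODE M21, which is on GRCm38, matched by symbol.

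The scripts were tested on simulated data in which 200 genes of the real libraries' means were changed. The changed genes were drawn only from those above a set mean CPM, so the rates below do not cover genes with lower counts. For sex over all cells 65 of 100 genes changed 2-fold and 99 of 100 changed 4-fold were found, with 21 false calls among 19216 genes. In enteric glia-like cells the counts were 63 and 100 of 100 with 15 false calls for sex, and 68 and 100 with 9 for day. For day in macrophage-like cells they were 90 and 100 with 19. For mesothelial-like cells against the other classes they were 72 and 100 with 1 false call among 3000 genes. In that simulation the classes otherwise shared the same means and a fixed dispersion, unlike the real classes. Set against the calls made, false calls exceeded the share that the adjustment threshold allows for sex over all cells, for sex in enteric glia-like cells and for day in macrophage-like cells. They were close to that share for day in enteric glia-like cells and below it for mesothelial-like cells. Calls for sex and day may thus hold more false ones than the threshold implies.

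Alternatives were edgeR's RLE factors, no filter on low counts, DESeq2 1.42.0, the libraries of 10 March alone or the females alone, no day term, each library left out, at most 10% mitochondrial UMIs, at least 1000 UMIs, no doublet removal, resolution 2, at least 50 cells per sum, all barcodes, clustering with the list genes, no animal block, and blood endothelial-like cells as the background class. For shares of cells with a UMI, each cell was thinned to 1000 UMIs and shallower cells were left out. Python 3.11.15, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9 were also used.

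With 42494325 to 71423603 UMIs per library, 1 UMI over a whole library is worth well under 1 CPM. The limit that 3 counts allow lay between 0.0508 and 0.0806 CPM over all cells. In the smaller classes the limit is higher, and such limits cover counting error only. No authors' annotation of cells was used here. The 19 neutrophil-like cells were too few to test, and the reads were not analysed here. Some genes that the rule names are not reported here.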

Results

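Transcripts of single cells from the muscle layer of the mouse colon were counted in 6 libraries, each labelled with the sex and birth date of a wild-type mouse. The layer holds the longitudinal muscle and the myenteric plexus, the network of nerve cells that drives gut movement. Of the 6 libraries, 4 were from females and 2 from males. On 10 March, 2 females and both males were processed at an age of 84 days, and on 3 March 2 further females were processed at 144 and 77 days. No treatment is labelled, so the comparisons that the design allows are between the sexes, between the days and between the cell types. The series title concerns inflammation, monocytes that are recruited to the plexus and the making of neurons. Group values are given as mean ± SD with n = 2 libraries per group unless said otherwise.

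The libraries of the 10 March females held 59346836 and 50240461 UMIs on 6684 and 8806 barcodes. Those of the males held 42494325 and 54373340 on 6003 and 7220 barcodes, and those of the 3 March females held 71423603 and 69343929 on 9371 and 9900. After filtering, 5363 and 7754 cells of the 10 March females, 4867 and 5926 of the males, and 7419 and 7614 of the 3 March females were kept. The median depth per cell was 6723 and 4084.5 UMIs in the 10 March females, 5643 and 6310 in the males, and 6353 and 6022.5 in the 3 March females. Between 200 and 546 cells per library were removed as likely doublets, or 3.95% to 6.58%.

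Fibroblast-like cells were the largest class, with 32.4 ± 3.15% of the cells in the 10 March females, 27.8 ± 2.82% in the males and 37.1 ± 6.72% in the 3 March females. Macrophage-like cells made up 13.8 ± 1.04%, 14.5 ± 1.69% and 13.8 ± 0.547% in the same order. Enteric glia-like cells, the support cells of the plexus, made up 5.05 ± 2.72%, 9.92 ± 1.22% and 8.75 ± 3.64%. Smooth muscle-like cells (2204 in all), mesothelial-like cells from the outer lining of the gut (1846), interstitial cell of Cajal-like cells, which pace the muscle (1839), blood endothelial-like (1695) and lymphatic endothelial-like cells (1640) followed. Immune classes were B cell-like (1518), T cell-like (1382), innate lymphoid and NK cell-like (622), dendritic cell-like (590), plasma cell-like (182), monocyte-like (171) and neutrophil-like cells (19). Pericyte-like (511), epithelial-like (269) and enteric neuron-like cells (253) completed the named classes. Enteric neuron-like cells were shallow, with a median of 939 UMIs against 8685 in fibroblast-like cells.

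All 11 enteric neuron markers, all 8 macrophage markers and all 9 mesothelial markers were highest in their own class, against 5 of 9 for monocyte-like and 7 of 9 for innate lymphoid and NK cell-like cells. Leading genes of the classes included Slpi, Upk3b and Msln in mesothelial-like cells, Kit and Ano1 in interstitial cell of Cajal-like cells, Fcna, F13a1 and Folr2 in macrophage-like cells, Nrg3, Rbfox1 and Syt1 in enteric neuron-like cells and Ly6c2 and Chil3 in monocyte-like cells. The 10 unnamed clusters held 7.82 ± 1.13% of the cells in the 10 March females, 7.76 ± 2.62% in the males and 7.14 ± 0.217% in the 3 March females. The largest (cluster 10, 1365 cells) was led by haemoglobin genes at a low depth and held 2.68 ± 2.75%, 4.2005 ± 2.72% and 4.16 ± 1.53%. Next came cluster 27 (426 cells), led by unnamed gene models, and a cluster of 363 cells, led by Lyz1, Retnla and Ccr2. The thresholds that kept clusters unnamed were set after the data were seen.

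**Figure D1:**
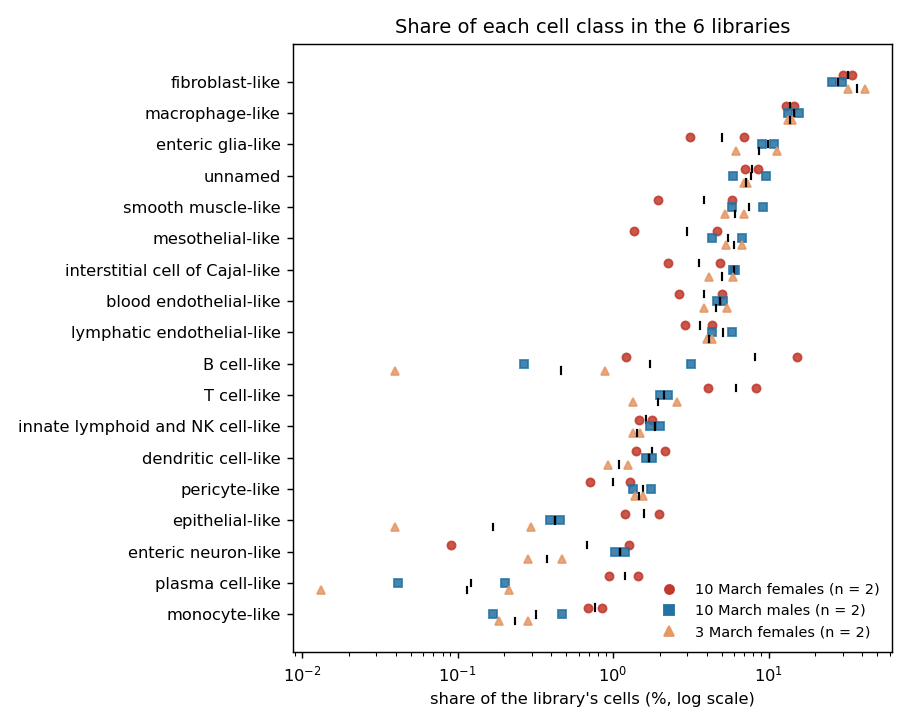
Share of each class in the cells of each library (percent, log scale), with points for libraries and black bars for the group means (n = 2 per group). B cell-like cells spread the most, from 0.0394% to 15.2% among the females, while macrophage-like cells stayed between 13.04% and 15.7% in all libraries.

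Cell shares were compared first, since the labels give sex and day as the differences between the mice. T cell-like cells made up 6.17 ± 2.98% in the 10 March females, 2.13 ± 0.178% in the males and 1.96 ± 0.873% in the 3 March females. Epithelial-like cells made up 1.58 ± 0.559%, 0.423 ± 0.0461% and 0.168 ± 0.182%, and monocyte-like cells 0.771 ± 0.114%, 0.321 ± 0.215% and 0.233 ± 0.0701%. In edgeR's test 0 of 17 classes were called for sex, with 2 at an unadjusted p under 0.05, of which T cell-like cells had a log2 difference of 1.53 ± 0.54 (SE) and an adjusted p of 0.349. For day 0 classes were called, with 4 at an unadjusted p under 0.05, and epithelial-like cells came closest with a log2 difference of 3.22 ± 0.93 (SE) and an adjusted p of 0.173. No other tool was run on the shares. Without 10 March female 1 a class was called for sex (count 1), and without 3 March female 3 the count for day was 2.

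The sex labels were checked on Xist, the RNA that silences an X chromosome in females, and on 4 genes of the Y chromosome. Xist (chromosome X, 103460366 to 103483254) stood at 1028 ± 71.5 CPM in the 10 March females and 974 ± 96.9 in the 3 March females. Male 1 had 0.215 CPM (8 UMIs) and male 2 had 9.70 CPM (457 UMIs). Ddx3y stood at 92.3 ± 6.38 CPM in the males, Eif2s3y at 63.9 ± 4.00, Kdm5d at 30.7 ± 0.0864 and Uty at 99.4 ± 2.82, while no female library held more than 4 UMIs of any of them. All 4 Y-linked genes were called lower in females over all cells. Xist itself had a log2 difference of 7.78 ± 1.44 (SE) with an adjusted p of 0.317 over all cells, and it was called in 11 of the 12 classes. It was called over all cells without either male library, in DESeq2, and when the male cells with at least 3 Xist UMIs were left out. Tsix, the antisense partner of Xist (chromosome X, 103431517 to 103484957), was called higher in females over all cells (log2 6.39 ± 0.18 SE, adjusted p 3.09e-04) and in all 12 classes. The labels do not say whether the counting used the strand, and Tsix spans Xist, so the UMIs of the pair were not separated here.

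Over all cells of a library 6 of 19463 genes were called for sex. They were the 4 Y-linked genes, Tsix, and the antibody light chain gene Igkv14-111, which was named after its values were seen and stood at 6.39 ± 0.967 CPM in the 10 March females and at 1 UMI or less in each other library. Plasma cell-like cells made up 1.1979 ± 0.363% in the 10 March females, 0.122 ± 0.114% in the males and 0.114 ± 0.143% in the 3 March females. In edgeR's test of the shares they were not called for sex (log2 3.25 ± 1.24 SE, adjusted p 0.349). For Igkv14-111 this share was not separated from expression, so its call need not be a difference in expression per cell. Unadjusted p was under 0.05 for 2180 genes, and DESeq2 called 347. The count was 674 without 10 March female 1 and 17 without 10 March female 2. Summed over the 12 classes tested, 152 calls were made for sex, 93 higher and 59 lower in females. The balance turned without the day term (59 higher, 106 lower), without female 1 (171 and 253) and without male 2 (56 and 74). Of these, 55 were of Xist and the 4 Y-linked genes and 97 of others, 12 of which were of Tsix, and the calls fell on 89 different genes. DESeq2 made 503 calls. The summed count was 424 without female 1, 256 without male 1, 243 without female 3 and 239 without female 4.

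Enteric glia-like cells held 36 sex calls, the most of any class, with 32 higher in females. Gbp2 (chromosome 3, 142620602 to 142638008), an interferon-induced GTPase, stood at 361 ± 106 CPM in the 10 March females, 79.0 ± 34.8 in the males and 77.6 ± 24.8 in the 3 March females. Psmb9, a subunit of the immunoproteasome (chromosome 17, 34181987 to 34187764), stood at 166 ± 24.8, 40.8 ± 6.79 and 43.5 ± 0.672 CPM in the same order. H2-Q6, a gene of the MHC class I family whose reads near-identical relatives can share, stood at 140 ± 39.4, 20.95 ± 0.891 and 25.4 ± 5.61 CPM. The sex differences within 10 March were log2 2.24 ± 0.30 (SE) for Gbp2 with an adjusted p of 0.00305, 2.07 ± 0.20 for Psmb9 with 8.95e-05 and 2.73 ± 0.24 for H2-Q6 with 4.03e-05. Zbp1, a sensor of nucleic acids (2.12 ± 0.33 SE, adjusted p 0.00922), and the antigen-loading gene H2-DMa (1.40 ± 0.24 SE, adjusted p 0.0216) were also higher. None of these 5 was called without the day term. For Gbp2, Psmb9 and H2-Q6 the 3 March females stood near the males, so only the 10 March females stood apart. Gbp2, Zbp1 and H2-DMa were not called without female 1, Zbp1 and H2-DMa not without male 2, and H2-DMa not without female 2 or male 1 or in DESeq2.

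Taken as a list, 15 interferon response genes were tested for sex in enteric glia-like cells, with 3 called and 11 adjusted over the list alone, and a median log2 difference of 0.97. Of 7 MHC class II genes 1 was called, 7 were higher when adjusted over the list alone, and the median was 2.02. Camera called both lists higher in females (adjusted p 3.1e-25 and 5.3e-18), and neither held with an estimated correlation (adjusted p 0.301 and 0.442).

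In mesothelial-like cells 32 genes were called for sex, 20 higher and 12 lower in females. Igf1 (chromosome 10, 87858265 to 87937042), a growth factor for nerve and muscle, stood at 556 ± 27.6 CPM in the 10 March females, 17.9 ± 13.6 in the males and 213 ± 124 in the 3 March females. Esr1, the oestrogen receptor (chromosome 10, 4611593 to 5005614), stood at 471 ± 37.1, 144 ± 14.4 and 225 ± 17.4 CPM. Rasgrp3, an activator of Ras, stood at 171 ± 6.17, 49.1 ± 1.22 and 106 ± 7.22 CPM. Adam23, a surface protein of neurons (chromosome 1, 63445891 to 63596276), went the other way with 7.32 ± 0.426, 87.2 ± 20.6 and 11.4 ± 3.07 CPM, as did the splicing factor gene Rbfox1 with 41.3 ± 2.15, 396 ± 94.8 and 55.1 ± 29.4 CPM, and Brinp2 with 4.48 ± 1.60, 41.8 ± 12.3 and 4.49 ± 0.623 CPM. The log2 differences were 4.91 ± 0.59 (SE) for Igf1 with an adjusted p of 0.0261, 1.70 ± 0.15 for Esr1 with 0.00612, 1.79 ± 0.14 for Rasgrp3 with 0.00207, -3.54 ± 0.27 for Adam23 with 0.00207, -3.28 ± 0.38 for Rbfox1 with 0.0229 and -3.41 ± 0.35 for Brinp2 with 0.0108. Igf1, Esr1 and Rasgrp3 were not called without the day term. Apart from Rasgrp3 none of the 6 was called without female 1 or without female 2, and Rbfox1 was also lost without male 1. Of the 9 steroid hormone response genes tested 1 was called, 4 were higher and 3 lower when adjusted over the list alone, and camera made no call (adjusted p 0.245).

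**Figure D2:**
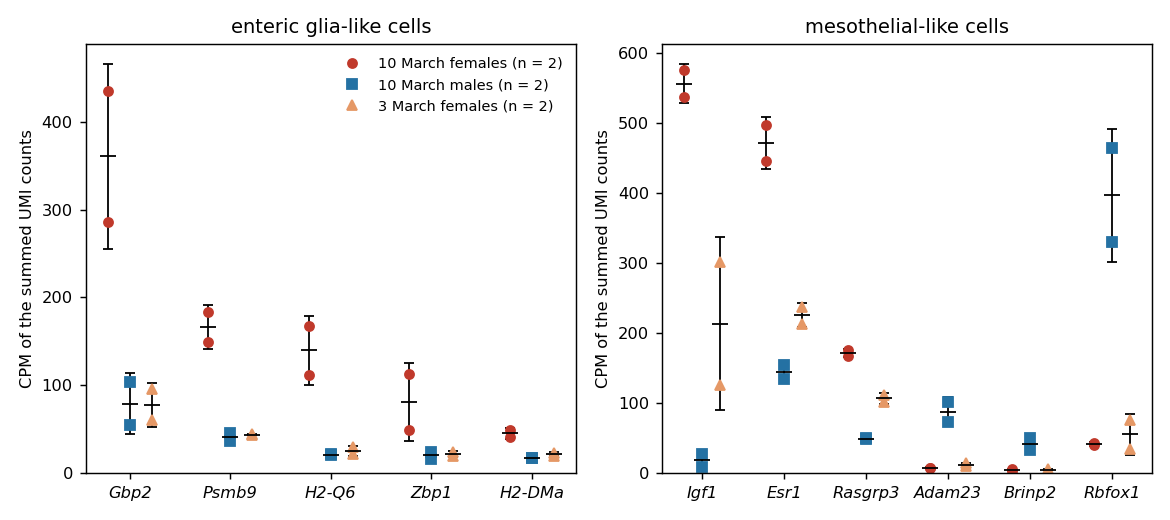
CPM of the summed UMI counts of 5 genes in enteric glia-like cells and 6 genes in mesothelial-like cells, with a point per library and bars for mean ± SD (n = 2 per group). Gbp2 in enteric glia-like cells stood at 361 CPM in the 10 March females against 79.0 in the males, and Rbfox1 in mesothelial-like cells at 41.3 against 396.

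Other classes held fewer sex calls. Interstitial cell of Cajal-like cells had 14, among them Tnfaip2, a gene induced by tumour necrosis factor, at 50.2 ± 8.69 CPM in the 10 March females, 9.52 ± 4.87 in the males and 14.1 ± 1.28 in the 3 March females. In the same cells Ifitm1 was higher in females (log2 1.47 ± 0.21 SE) and the transcription factor gene Hand1 was lower (-1.53 ± 0.25 SE), each lost without female 1, female 2 or male 2, and Tnfaip2 was lost without female 1 or 2. Lymphatic endothelial-like cells had 12, with Parm1 at 100 ± 1.41, 19.2 ± 0.434 and 53.3 ± 12.6 CPM (log2 2.39 ± 0.19 SE, adjusted p 7.98e-04) and the vessel gene Plvap at 153 ± 6.32, 61.1 ± 3.97 and 101 ± 1.27 CPM. Plvap was not called without male 1 or male 2. In innate lymphoid and NK cell-like cells the glutamate receptor gene Grik2 stood at 46.6 ± 2.61 CPM in the 10 March females, 290 ± 4.66 in the males and 139 ± 36.3 in the 3 March females (log2 -2.62 ± 0.26 SE, adjusted p 1.09e-04). Parm1, Plvap, Tnfaip2, Ifitm1 and Grik2 were not called without the day term. Rad51b was higher and Prnp lower in females in the innate lymphoid and NK cell-like cells, and both were lost in the libraries of 10 March alone and without female 1, female 2 or female 4, Prnp also without male 2 or female 3.

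Macrophage-like cells had 6 sex calls, and 5 of them were Tsix and the 4 Y-linked genes. The other was Ccl7, a chemokine that draws monocytes (chromosome 11, 82045712 to 82047525), at 208 ± 20.5 CPM in the 10 March females, 99.2 ± 11.4 in the males and 148 ± 8.70 in the 3 March females (log2 1.10 ± 0.14 SE, adjusted p 0.0368). It was lost without any library except male 1. Of the 7 monocyte recruitment and survival ligands tested there 1 was called, 4 were higher when adjusted over the list alone, and camera called the list (adjusted p 3.9e-07) but not with an estimated correlation (adjusted p 0.301). In dendritic cell-like cells Iigp1, an interferon-induced GTPase, stood at 119 ± 12.5, 7.63 ± 7.37 and 2.62 ± 2.33 CPM (log2 3.92 ± 0.43 SE, adjusted p 0.00334), and was lost without the day term. Ly6a was higher and Syn3 lower there, and in T cell-like cells St8sia1 was higher and Nlgn1 lower. Nlgn1 and Syn3 were lost without any of the 6 libraries, St8sia1 without male 1, male 2, female 3 or female 4, and Ly6a without female 1, female 2 or male 2.

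In fibroblast-like cells haemoglobin genes led the sex calls besides the sex-linked genes. Hbb-bs stood at 148 ± 13.8 CPM in the 10 March females, 48.9 ± 4.02 in the males and 204 ± 24.1 in the 3 March females, against 3950.4 ± 2455 (n = 6) in blood endothelial-like cells. Hba-a1, Hba-a2 and Hbb-bt were called with it (each with an adjusted p of 0.0199), and Saa3, an acute phase gene, was called at 6.41 ± 1.69, 0.294 ± 0.0517 and 1.91 ± 0.666 CPM. Saa3 was lost without any library except female 1. All 4 haemoglobin calls were lost in the libraries of 10 March alone and without male 1, male 2, female 3 or female 4. Hbb-bs, sex, fibroblast, log2 fold change was 1.66 and turned to -0.0728 with no doublet removal, and was 0.00768 with at most 10% mitochondrial UMIs and 0.0886 with at least 1000 UMIs per cell. Main clusters differed here, with cluster 5 leading the class in the 10 March females, cluster 0 in the 3 March females and cluster 2 in the males.

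Day was compared to show how far libraries of females made on different days differ, with age and day inseparable for the older mouse. Over all cells 4 genes were called, 3 higher and 1 lower on 10 March, 2872 had an unadjusted p under 0.05, and DESeq2 called 857. Hal, which encodes the enzyme that breaks down histidine (chromosome 10, 93488768 to 93519304), stood at 0.648 ± 0.192 CPM in the 10 March females, 1.15 ± 0.192 in the males and 252 ± 73.2 in the 3 March females (log2 -8.56 ± 0.34 SE, adjusted p 0.00459). The 3 higher genes, named after their values were seen, were the zinc finger gene Zfp990 and the antibody genes Igkv14-111 and Igkv3-2. For these antibody genes too, the share of plasma cell-like cells, given with the sex contrast, was not separated from expression. Hal was not called in the females alone or without male 1 or male 2. The count was 958 without female 1, 75 without female 2, 0 without male 1 or male 2 and 1 without female 4. Per class 365 calls were made for day in 7 of the 12 classes, 170 higher and 195 lower on 10 March, on 288 different genes. The balance turned in DESeq2 (388 higher, 325 lower), in the females alone (423 and 346), and without female 2 (134 and 64), male 1 (422 and 332), male 2 (459 and 331) or female 3 (163 and 147). It also turned with no low-count filter (1985 and 1714), at most 10% mitochondrial UMIs (233 and 212), at least 1000 UMIs (307 and 269), no doublet removal (122 and 119) and resolution 2 (232 and 230). DESeq2 made 713 calls, and the count was 198 without female 2, 754 without male 1, 790 without male 2 and 109 without female 4.

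Macrophage-like cells held 122 of the day calls. Hal had 2, 1, 0 and 1 UMIs in the macrophage-like cells of the 10 March libraries, and 15225 and 10588 in those of 3 March (1796 ± 566 CPM). Of the macrophage-like cells of 3 March female 3, 718 of 995 held a Hal UMI (72.2%, exact 95% interval 69.3 to 74.9%), and of female 4 535 of 1080 (49.5%, 46.5 to 52.6%). In the males and females of 10 March the shares were 0.257% or less. The fitted log2 difference of -12.70 ± 0.42 (SE, adjusted p 1.3e-06) depends on the prior count and is no bound. Genes beside Hal on chromosome 10 were called too. Amdhd1, the next enzyme but one of the same pathway (93523338 to 93540033), stood at 0.333 ± 0.0747 CPM in the 10 March females, 0.179 ± 8.91e-04 in the males and 30.9 ± 13.5 in the 3 March females. Lta4h (log2 -1.53 ± 0.12 SE) was lower and Fgd6 (1.56 ± 0.15) and Vezt (0.75 ± 0.14) were higher on 10 March, with adjusted p of 0.00129, 0.00343 and 0.0441, and Lta4h and Vezt were named after their values were seen. Hal, Amdhd1 and Fgd6 were called under all 16 alternatives run for these cells.

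**Figure D3:**
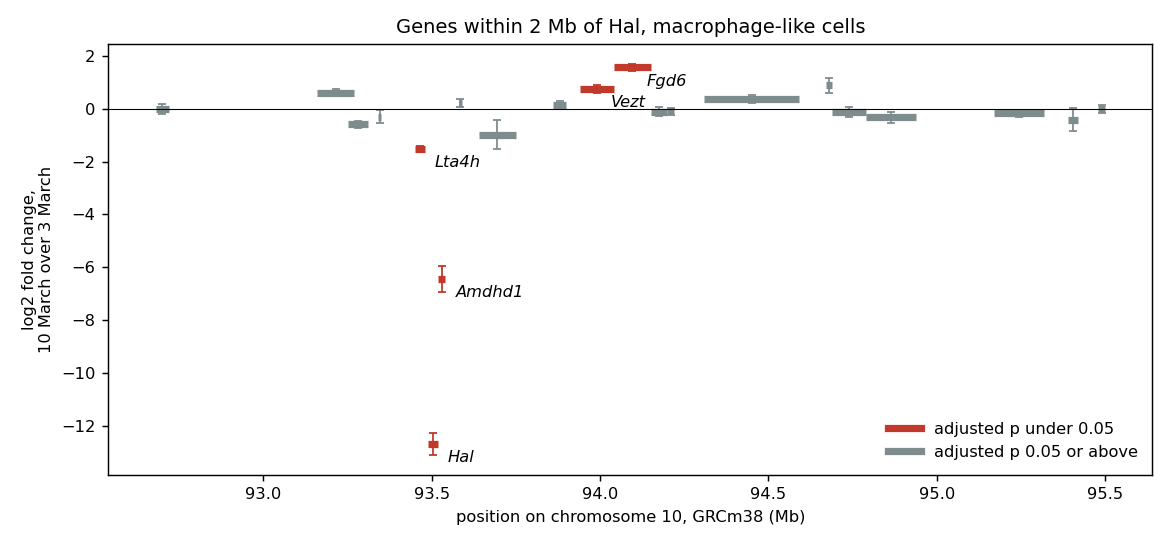
Log2 fold change of 10 March over 3 March (with SE) in macrophage-like cells against position on chromosome 10 (GRCm38, Mb), for the 21 genes tested within 2 Mb of Hal, with called genes in red. Hal fell by 12.70 and Amdhd1 by 6.45 on the log2 scale, while Fgd6 was higher by 1.56.

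Further genes differed between the days in other classes and on other chromosomes. Rab6b, a regulator of vesicle transport (chromosome 9, 103111787 to 103185276), was called lower on 10 March in 5 classes. In macrophage-like cells it stood at 2.01 ± 1.25 CPM in the 10 March females, 2.95 ± 0.647 in the males and 41.0 ± 9.81 in the 3 March females, and in enteric glia-like cells at 5.43 ± 0.553, 5.33 ± 0.754 and 54.9 ± 9.78. Its call was lost without female 1 in lymphatic endothelial-like cells and without female 2, 3 or 4 in innate lymphoid and NK cell-like cells. Zfp990 was called higher on 10 March in T cell-like, dendritic cell-like and innate lymphoid and NK cell-like cells. It stood at 37.9 ± 22.8 CPM in T cell-like cells of the 10 March females, 70.2 ± 4.30 in the males and 0.624 ± 0.882 in the 3 March females, and the call there was lost without female 3 or female 4, that in innate lymphoid and NK cell-like cells without female 4. Cfap54, on the chromosome of Hal and within 2 Mb of it (chromosome 10, 92775619 to 93081618), was lower in lymphatic endothelial-like and smooth muscle-like cells, and the creatine kinase gene Ckb was lower in the lymphatic endothelial-like cells. The smooth muscle-like call was lost without female 1, 3 or 4. In the lymphatic endothelial-like cells Cfap54 was lost without any library, and Ckb without any except female 3. Main smooth muscle-like clusters were 17 in the 10 March females and the males and 16 in the 3 March females.

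The day calls included the following genes in macrophage-like and enteric glia-like cells. In macrophage-like cells Fcgr4, an antibody receptor, stood at 224 ± 27.3 CPM in the 10 March females, 135 ± 28.1 in the males and 52.8 ± 1.90 in the 3 March females. In enteric glia-like cells Fcgr2b, another antibody receptor, stood at 380 ± 10.1, 373 ± 2.95 and 63.8 ± 0.707 CPM (log2 2.59 ± 0.18 SE, adjusted p 9.19e-06). In dendritic cell-like cells Fcgr2b was called the other way, lower on 10 March, and the median log2 difference over both classes was 0.688. H2-Ab1, an MHC class II chain, stood at 247 ± 84.4, 56.7 ± 36.5 and 51.5 ± 35.3 CPM in enteric glia-like cells. Glial Gbp2, H2-Q6 and Psmb9, whose group values are given with the sex contrast, were called for day as well, with log2 differences of 2.27 ± 0.30 (SE), 2.48 ± 0.23 and 1.97 ± 0.19. Both contrasts use the same 10 March females and are not independent. Of these genes Fcgr4 in macrophage-like cells and the glial Fcgr2b, Gbp2, H2-Q6 and Psmb9 were called under all 16 alternatives. H2-Ab1 was lost without female 2 or 4 and in DESeq2. Klra2, Ifit2, Rsad2 and the class II regulator Ciita were also higher in macrophage-like cells (all lost without female 4, Ifit2 also without female 1 or 3, Rsad2 without female 1 or 2, Ciita without any female), as were Zbp1 and Ifit3 in enteric glia-like cells (lost without female 1 or 4), and Nlrc5 in smooth muscle-like cells (lost without female 1, 3 or 4).

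As a list, 15 interferon response genes were tested for day in enteric glia-like cells, with 5 called, 10 higher when adjusted over the list alone and a median of 1.11. In macrophage-like cells 16 were tested, 3 were called, 12 were higher and 1 lower when adjusted over the list alone, and the median was 1.06. In smooth muscle-like cells 12 were tested, 1 was called, 9 were higher when adjusted over the list alone, and the median was 1.61. Camera called the list higher in these 3 classes (adjusted p 3.4e-30, 6.3e-14 and 1.6e-22) but not with an estimated correlation (adjusted p 0.301, 0.528 and 0.381). In mesothelial-like cells camera called it lower (median -0.31, 0 of 16 called, adjusted p 0.0402, and 0.842 with an estimated correlation). For MHC class II, 1 gene was called in each of enteric glia-like, macrophage-like and T cell-like cells, and 6, 7 and 4 were higher when adjusted over the list alone, with adjusted p of 0.442, 0.528 and 0.454 for the list with an estimated correlation. Dendritic cell-like cells, where these genes were highest, went the other way, with a median of -0.38, 0 of 7 called, 5 lower when adjusted over the list alone and a camera call lower (adjusted p 0.00485) that was lost with an estimated correlation (adjusted p 0.598). All 7 genes were called lower in enteric glia-like and in T cell-like cells than the mean of the other classes. No correction for free RNA was made, so free RNA of cells rich in these genes was not separated from expression there.

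T cell-like cells had 78 day calls, 68 of them lower on 10 March. Genes of smooth muscle and pericytes were among the lower ones and are given below. Il17rb, the receptor for interleukin 25 (chromosome 14, 29996135 to 30008896), stood at 4.25 ± 1.97 CPM in the 10 March females, 8.76 ± 4.47 in the males and 138 ± 33.9 in the 3 March females (log2 -5.03 ± 0.38 SE, adjusted p 1.82e-04). Il1rl1, the receptor for interleukin 33 (chromosome 1, 40429570 to 40465415), stood at 8.49 ± 1.74, 23.0 ± 6.08 and 93.6 ± 5.25 CPM, and Amph, an endocytosis gene, at 9.47 ± 3.70, 20.6 ± 2.58 and 142 ± 24.3. All 3 were called under every one of 16 alternatives. Gata3, Il4, Il9r, Il5 and Il13 were named after their values were seen and tested as no list. Each was called lower as well, with Gata3 at 56.2 ± 14.0, 76.6 ± 28.9 and 159 ± 10.2 CPM. The class was led by cluster 20 in the 10 March females and the males and by cluster 30, with Cd163l1 and Trdc, in the 3 March females. Prkch, Insyn2b and Cd74 were higher on 10 March and were lost without female 2, 3 or 4, Insyn2b also without female 1.

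Dendritic cell-like cells had 78 day calls, 33 higher and 45 lower on 10 March. Serpinb6b, a protease inhibitor, stood at 149 ± 7.14 CPM in the 10 March females, 74.5 ± 12.7 in the males and 10.97 ± 10.7 in the 3 March females (log2 3.76 ± 0.40 SE, adjusted p 0.0065). Iigp1 and Bcl2l14 were higher too, each lost without female 3, and Cxcl10, lost without female 2, 3 or 4, had 0 UMIs on 3 March. Bckdhb (38.3 ± 3.63, 66.0 ± 0.820 and 110 ± 3.20 CPM) and Gfra2, a receptor for neurturin, were lower, both lost without female 2 or 3. In innate lymphoid and NK cell-like cells Lrmda stood at 216 ± 37.3 CPM in the 10 March females, 183 ± 109 in the males and 36.2 ± 0.319 in the 3 March females, a call lost without female 2, 3 or 4.

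Genes of smooth muscle and pericytes were measured outside those cells in these contrasts. Acta2, Actg2, Myl9, Mylk and the pericyte gene Rgs5 were called lower on 10 March, Actg2 and Myl9 being named after their values were seen, in T cell-like, dendritic cell-like, innate lymphoid and NK cell-like and macrophage-like cells. Further muscle genes, among them Myh11, Tpm2, Des and Tagln, were called for day in T cell-like and innate lymphoid and NK cell-like cells. Their median log2 differences over the classes that called them were -1.81, -2.24, -2.02 and -2.10, and they were named after their values were seen. Free RNA of muscle cells and pericytes was not separated from expression in these classes, whose day counts include such genes. In the innate lymphoid and NK cell-like cells Acta2 stood at 98.6 ± 48.2 CPM in the 10 March females, 171 ± 32.0 in the males and 462 ± 36.9 in the 3 March females, and in macrophage-like cells at 88.5 ± 45.7, 150 ± 33.4 and 364 ± 90.2, against 9067.5 CPM in smooth muscle-like cells. Rgs5 stood at 26.0 ± 5.14 CPM in dendritic cell-like cells of the 10 March females, 38.6 ± 2.09 in the males and 96.1 ± 19.99 in the 3 March females, a call lost without female 2, 3 or 4. The calls for Acta2 and Mylk in the innate lymphoid and NK cell-like cells were lost without female 2 or female 4. In enteric glia-like cells Cxcl14, Plac9b and Ccl5 were called at low counts, each lost without female 1 or 4, Plac9b also without female 2. In edgeR 0 genes were called for day in 5 classes, with unadjusted p under 0.05 for 1225 genes in mesothelial-like, 1140 in fibroblast-like, 767 in blood endothelial-like, 579 in interstitial cell of Cajal-like and 243 in pericyte-like cells.

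The sources of signals that reach the plexus were compared across the 17 classes. Of 24 neurotrophic and niche ligands 21 were called above the mean of the other classes in fibroblast-like cells. The count was 20 in interstitial cell of Cajal-like, 19 in smooth muscle-like and 16 in mesothelial-like cells. By mean CPM 7 of the 24 were highest in interstitial cell of Cajal-like cells. Among the others, Slit3 stood at 2073 ± 503 CPM in fibroblast-like cells (log2 5.23 ± 0.23 SE above the mean of the other classes), Sema3c at 1204 ± 152 in mesothelial-like cells (5.13 ± 0.12) and Sema3a at 673 ± 71.3 in smooth muscle-like cells (6.03 ± 0.12). Kitl, the ligand of Kit, stood at 815 ± 87.9 CPM in blood endothelial-like cells (3.73 ± 0.12). Among 10 ligands that recruit or sustain monocytes, Cxcl12 stood at 1904 ± 168 CPM in blood endothelial-like cells, Ccl8 at 1608 ± 776 and Ccl12 at 289 ± 71.6 in macrophage-like cells, and Il34 at 284 ± 46.5 in pericyte-like cells (SD, n = 6 libraries each). All of these were called above the mean of the other classes.

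Among 20 inflammatory cytokines and chemokines, Ccl5 stood at 1760 ± 1159 CPM in T cell-like cells, Lcn2 at 1038 ± 197 in lymphatic endothelial-like cells and Ccl11 at 563 ± 325 in pericyte-like cells (n = 6), and Cxcl9 at 780 ± 903 in monocyte-like cells (n = 4). All 7 MHC class II genes were highest in dendritic cell-like cells, with Cd74 at 15078 ± 2045 CPM, H2-Ab1 at 7177 ± 798, H2-Eb1 at 6368 ± 730 and H2-Aa at 5828 ± 724. Of 12 genes of resident muscularis macrophages 9 were highest in macrophage-like cells, with Apoe at 14089 ± 3131 CPM, Retnla at 4557 ± 2459 and Selenop at 3827 ± 474, while Lyve1 stood at 3923 ± 529 in lymphatic endothelial-like cells and at 775 in macrophage-like cells. Over these 5 lists 361 calls above the mean of the other classes were made, with 126, 50, 86, 43 and 56 per list in the order given, against 125, 48, 79, 42 and 61 adjusted over the list alone.

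The 15 MEN genes, linked in earlier work to enteric neurons of mesodermal origin, were compared in the same way to find the class that holds their transcripts. In mesothelial-like cells Slpi stood at 4054 ± 418 CPM (chromosome 2, 164354070 to 164389095), Fmo2 at 2552 ± 711, Aebp1 at 2518.5 ± 200, Cdh3 at 186.5 ± 50.8, Met at 139 ± 21.7 and Clic3 at 46.6 ± 17.6 (n = 6). Dcn, a matrix gene, was highest in fibroblast-like cells and reached 10958 CPM in mesothelial-like cells. Calcb, a neuropeptide gene (210 ± 141 CPM, n = 5, against 2.48 in mesothelial-like cells), Stx3 and Vsnl1 were highest in enteric neuron-like cells, and Slc17a9 in B cell-like cells. All 15 genes were called above the mean of the other classes in mesothelial-like cells, against 7 in smooth muscle-like cells, 6 each in enteric neuron-like, epithelial-like and lymphatic endothelial-like cells and 5 in fibroblast-like cells. In mesothelial-like cells the log2 differences were 8.46 ± 0.16 (SE) for Slpi, 8.85 ± 0.22 for Clic3 and 8.20 ± 0.19 for Cdh3. Over all classes 78 calls were made, 79 adjusted over the list alone.

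**Figure D4:**
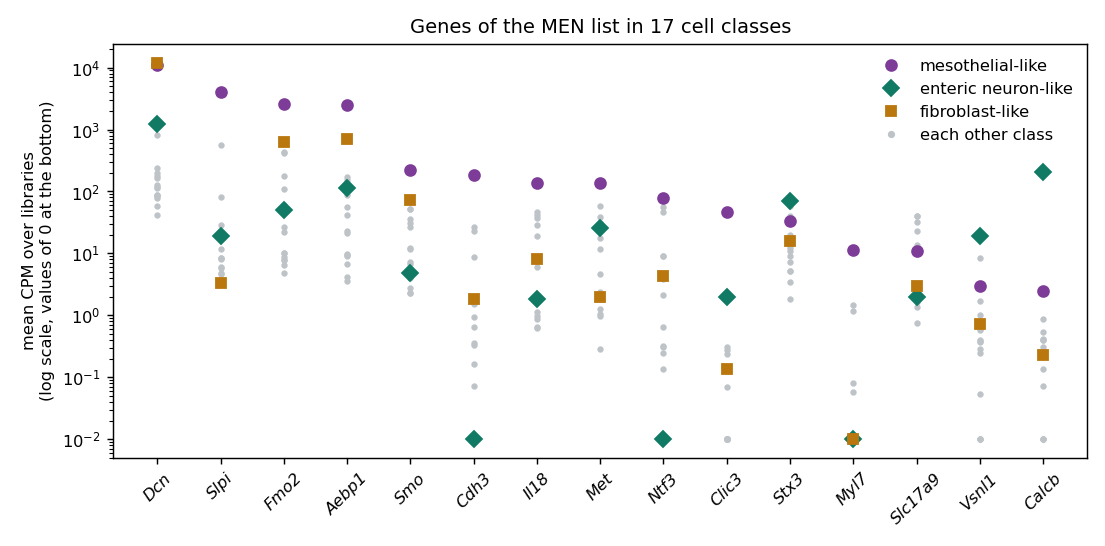
Mean CPM over libraries (log scale) of each of the 15 MEN genes in 17 classes, with mesothelial-like, enteric neuron-like and fibroblast-like cells marked. Of the 15 genes 10 were highest in mesothelial-like cells, such as Slpi at 4054 CPM, and Calcb stood at 210 CPM in enteric neuron-like cells.

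General neuronal genes were then compared between myeloid and lymphocyte-like cells, since the title names neurogenic monocytes and lymphocytes served as the class that should lack these transcripts. All 16 genes of the list were highest in enteric neuron-like cells, with Syt1 at 1542 ± 729 CPM, Stmn2 at 752 ± 383, Snap25 at 638 ± 163 and Rab3c at 625 ± 252 (n = 5). In macrophage-like cells 10 of the 16 had enough counts to test, and Syn1 and Syp were called higher than in lymphocyte-like cells. Syn1 (chromosome X, 20860511 to 20921004), a protein of synaptic vesicles, stood at 7.13 ± 2.01 CPM in macrophage-like cells (268 UMIs) and 0.697 ± 1.14 in lymphocyte-like cells (12 UMIs), against 119 ± 44.5 in enteric neuron-like cells. Syp (chromosome X, 7638471 to 7653256), another vesicle protein, stood at 6.76 ± 2.07 (261 UMIs), 1.01 ± 1.16 (15 UMIs) and 193 ± 135 CPM. The log2 differences were 3.05 ± 0.49 (SE, adjusted p 2.83e-04) and 2.47 ± 0.48 (SE, adjusted p 9.90e-04). The median of the 10 genes was 0.020, and both counts adjusted over the list alone were the same (2). Against the mean of the other classes, 3 of the 16 were called higher in macrophage-like cells. The count was 8 in enteric glia-like, 6 in fibroblast-like, 5 in blood endothelial-like and 4 in pericyte-like cells. With libraries pooled, Syp stood at 6.87 CPM in macrophage-like, 6.83 in fibroblast-like, 13.9 in pericyte-like and 25.9 in enteric glia-like cells.

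In monocyte-like cells Syn1 was the only gene of the list with enough counts to test, at 16.0 ± 6.35 CPM (n = 4, 17 UMIs), with a log2 difference of 4.38 ± 1.03 (SE, adjusted p 0.00327) from lymphocyte-like cells. That call was lost with cells of at least 1000 UMIs and with no doublet removal, and Syn1 could not be tested without 3 March female 3 or without the animal block. The monocyte-like class was a part (171 cells) of a split cluster. Other parts of that cluster, with 363, 249, 189, 140 and 17 cells, stayed unnamed and were not tested. Unnamed cells of all clusters held 293 Syn1 UMIs at 21.2 CPM. Shares of cells with a Syn1 UMI were 3.40% in macrophage-like (median 6842 UMIs), 3.51% in monocyte-like (7926) and 3.82% in fibroblast-like cells (8685). Unnamed cells reached 6.01% (2022 UMIs, 1.51% thinned) and dendritic cell-like cells 5.25% (12068 UMIs, 0.171% thinned). The shares were 0.289% in T cell-like (3434 UMIs) and 0.395% in B cell-like cells (2864), and 15.4% in enteric neuron-like cells (939). Thinned to 1000 UMIs per cell the shares were 0.682% in macrophage-like, 0.595% in monocyte-like, 0.490% in fibroblast-like, 0.0787% in T cell-like, 0.0727% in B cell-like and 14.0% in enteric neuron-like cells. The cells deep enough for thinning numbered 4840 macrophage-like, 168 monocyte-like and 584 dendritic cell-like. They numbered 1271 T cell-like, 1376 B cell-like and 114 enteric neuron-like. The smallest shares thus rest on very few cells and rank no classes. Thinned shares of Syp were 0.909% in macrophage-like, 2.23% in enteric glia-like and 0.0787% in T cell-like cells.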

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

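In this part the tests of genes near Hal, of the Xist-bearing cells' share of the library's Xist UMIs and their Y-linked UMIs, of Cfp beside Syn1 and of Syt1 beside Syn1 were chosen only after the result was seen, as was the minimum of 30 UMIs in the Syp test.

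A library far from the other females was found in 3 of 120 tests over the 4 females, and chance picks out about 1 in 20 groups, or 6 here. Female 1 had 5363 cells against 7419 to 7754 in the others. Female 2 had 15.2% B cell-like cells against 0.0394% to 1.21%. In smooth muscle-like cells of female 3 Xist stood at 932 CPM against 660 to 689 in the others.

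Genes whose sex or day effect in a class differed from the mean effect in the other classes were picked out by a test of that difference. For sex it called 55 genes in mesothelial-like, 9 in T cell-like, 5 in fibroblast-like and 0 or 1 in each other class. For day it called 87 in T cell-like, 38 in mesothelial-like, 20 in smooth muscle-like, 16 in dendritic cell-like, 13 in macrophage-like and 0 to 2 in each other class. Those given here are the ones that the rule for naming genes also names in that class. In mesothelial-like cells the sex effect of Esr1 was higher by log2 1.75 (adjusted p 2.2e-04) and that of Igf1 by 4.71 (adjusted p 4.9e-11). The day effect of Amph differed by -3.61 in T cell-like cells (adjusted p 0.0319). In dendritic cell-like cells that of Serpinb6b differed by 3.73 (adjusted p 1.0e-06) and that of Bckdhb by -1.49 (adjusted p 1.5e-04). In innate lymphoid and NK cell-like cells Lrmda differed by 2.13 (adjusted p 0.0447).

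Hal was nearly absent from macrophage-like cells on 10 March. Of 20 other genes tested within 2 Mb of it 4 were called for day, a number reached by 0.940% of windows of that size, which is consistent with a difference in the local haplotype between the mice. A different make-up of the macrophage-like cells predicts that markers of Hal-bearing cells fall with Hal. Their median log2 change was -0.275, in a range of -1.77 to 0.605 with 2 of 20 called lower (Ccl24 and Aff3). Hal's own change (-12.70) is no measure for them, since they were only log2 2.47 to 5.84 higher in Hal-bearing than in Hal-free cells. The markers thus largely remained on 10 March while Hal did not, and a part played by make-up was not excluded. Preparation or depth predicts like changes in genes of like level, and the largest among 103 was 1.13 (Ccl8). Age alone does not order the libraries, since Hal stood at 1396 CPM at 77 days and 2196 at 144 days but at 0.280 or less in the 4 libraries at 84 days. The comparison with those 103 genes covers only effects of preparation or depth that genes of Hal's level share. In the same cells Rab6b, at a lower level, changed by log2 -4.38. The strain is not labelled, and other differences between the days, with preparation effects on single genes among them, remain open and untested.

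Male 2 held 457 Xist UMIs. Free RNA would spread them over many cells, but 95.2% lay in 37 cells with at least 3. Doublets of a male and a female cell would hold Y-linked UMIs, but 31 of the 37 held none, against 4.48 expected. Cells of a 3 March female would often hold Hal, but 0 of 12 macrophage-like ones did, against 7.25 expected (exact binomial p 1.5e-05), and 0 of the 37 barcodes occurred in a female library. Cells of a 10 March female could remain as a source, and that was not tested.

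Syn1 in macrophage-like cells could come from transcripts that run on from Cfp, which ends 4450 bp upstream on the same strand. Cells with Syn1 held 1.56 times the Cfp UMIs of like cells without it, at percentile 98.8 of 897 genes, short of the 99 set for a decision. Syp cells held 1.30 times the Cacna1f UMIs, at percentile 78.0, and rested on 12 Cacna1f UMIs. The Syp result met the condition written beforehand for rejecting run-on, but a minimum of 30 UMIs was added after the value was seen because 12 are too few to tell, so both cases stay undecided. Free RNA of neurons predicts as much Syt1 per Syn1 as in neuron-like cells (14.4), but the ratio was 0.261, and no biological explanation was tested.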

How the results depend on the processing

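Leaving out male cells with Xist was chosen only after the result was seen. In leave-one-out fits the lone library of a group was assumed to vary like the others. For sex over all cells (6 calls) no low-count filter gave 12, DESeq2 347 and leave-one-out 4 to 674. For sex per class (152) no filter gave 2522, DESeq2 503, at most 10% mitochondrial UMIs 235, at least 1000 UMIs 325 and leave-one-out 130 to 424. For day over all cells (4) no filter gave 34, DESeq2 857, the females alone 0, all barcodes 1 and leave-one-out 0 to 958. For day per class (365) no filter gave 3699, DESeq2 713, the females alone 769, at least 1000 UMIs 576, no doublet removal 241 and leave-one-out 109 to 790. Calls on shares (0) were 0 to 1 for sex and 0 to 2 for day in leave-one-out, and 1 for day at resolution 2. Of 129 camera calls 2 held with an estimated correlation, and fry made 5. The monocyte-like count (1) was 0 with no animal block, with at least 1000 UMIs and with no doublet removal, and 0 to 1 in leave-one-out. The cause was not tested.

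Counts that stayed close to their value under every alternative were those of the signalling lists (361 calls, leave-one-out 315 to 358), the MEN genes (78, leave-one-out 71 to 79; in mesothelial-like cells 15, leave-one-out 15 to 15) and the macrophage-like count of 2 higher genes. Whether the same list genes made up each count was not compared, and lower genes in macrophage-like cells went from 0 to 4 with no doublet removal and to 5 against blood endothelial-like cells (median -1.23). Values that changed sign or reached 0 were the following. Hbb-bs, sex, fibroblast, log2 fold change was -0.0728 with no doublet removal. Xist, day, all cells, log2 fold change was -0.00929 without female replicate 2 and -0.0256 without female replicate 4 (leave-one-out -0.0256 to 0.224). For the Y-linked genes, leave-one-out gave -1.71 to 0.0685 for Ddx3y, day, all cells, log2 fold change, 0 to 3.17 for Eif2s3y, day, all cells, log2 fold change, and -3.85 to 0 for Kdm5d, day, all cells, log2 fold change, so that the last pair reached 0 without changing sign. Hbb-bt, haemoglobin, enteric neuron-like against the other classes, log2 fold change was -1.46 to 4.55 in leave-one-out and -0.840 with list genes kept in the clustering. The cause was not tested. Of the values of named genes in the contrasts 2103 were the same, 301 weaker, 4 stronger and 6 reversed or at 0, and across classes 953 were the same, 14 weaker and 2 reversed. Of the list values 7 were the same and 251 weaker, and of the shares 67 were the same and 5 moved. At least 50 cells per sum could not be run for monocyte-like cells. Depth limits the enteric neuron-like cells most (median 939 UMIs). No paired analysis was possible because replicate numbers were assigned here and the sexes are different animals.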

Other observations

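In this part no test was chosen only after the result was seen, and the gene lists below were fixed beforehand.

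Cycling cells and clock genes were measured across the classes. The cell cycle genes Mki67 (707 ± 410 CPM) and Top2a (550 ± 337) were highest in epithelial-like cells (n = 4). The clock gene Npas2 stood at 189 ± 27.9 in interstitial cell of Cajal-like cells (n = 6).

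In the class comparison calls above the mean of the other classes numbered 106 for interferon response, 51 for cell cycle, 83 for circadian clock, 62 for steroid hormone response, 88 for immediate early and dissociation genes, 38 for heat shock, 26 for haemoglobin, 12 for adipocyte and 10 for sex-linked genes. Adjusted over the list alone the counts were 107, 53, 83, 63, 92, 38, 27, 12 and 8. For neurotrophic and niche ligands, monocyte ligands, inflammatory genes, MHC class II, resident macrophage, MEN and pan-neuronal genes the calls were 126, 50, 86, 43, 56, 78 and 56.

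In the sex and day contrasts camera was run on each list over all cells and per class. For sex, interferon response was called higher in 10 and lower in 1 of 13, MHC class II higher in 7 of 13, heat shock higher in 8 of 13, inflammatory genes higher in 6 of 11, monocyte ligands higher in 6 of 12, neurotrophic ligands higher in 3 of 13, cell cycle higher in 3 of 9 and immediate early genes higher in 3 and lower in 1 of 13. Haemoglobin was higher in 2 and lower in 2 of 10, resident macrophage genes higher in 1 and lower in 3 of 13, steroid hormone response higher in 1 of 13, MEN genes lower in 1 of 13, pan-neuronal genes lower in 1 of 9, adipocyte genes lower in 1 of 3, the clock in 0 of 13 and sex-linked genes lower in 13 of 13. With an estimated correlation only the sex-linked list was called for sex (2 of 13, adjusted p 0.0322 at the lowest), and all the other sex calls above were lost.

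For day, interferon response was called higher in 12 and lower in 1 of 13, MHC class II higher in 11 and lower in 1 of 13, inflammatory genes higher in 6 of 11, immediate early genes higher in 4 and lower in 1 of 13, cell cycle higher in 3 of 9 and haemoglobin higher in 3 and lower in 3 of 10. Resident macrophage genes were lower in 3 of 13, MEN genes lower in 2 of 13, pan-neuronal genes lower in 1 of 9, monocyte ligands higher in 1 of 12, heat shock and the clock higher in 1 of 13 each, steroid hormone response higher in 1 and lower in 1 of 13, and neurotrophic ligands, adipocyte and sex-linked genes in 0. With an estimated correlation no list was called for day.

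Class labels were shuffled or sums regrouped to count how often as many calls arose. For the signalling lists 1 of 21 arrangements, the real one, reached 359 calls on 585 genes, a set reduced to save computing time, and the highest other gave 52. For the MEN genes it was 1 of 21, with 78 against 21. For general neuronal genes it was 1 of 50 in macrophage-like cells (2 against 0) and 1 of 50 in monocyte-like cells (1 against 0). Clustering of the same counts had already separated these classes, and mixed labels put their differences into the spread. Fewer calls under mixed labels therefore say nothing particular to these lists, and no random list was counted beside them.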
